A study of Mus musculus with 15 samples.

How the data were processed

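The samples were 15 polyadenylated RNA libraries from left ventricles of C57BL/6 mice after experimental myocardial infarction. Per the labels' protocols, ventricles were kept in RNAlater, RNA was purified with the RNeasy Plus Micro kit, and stranded libraries were made with oligo-dT capture (TruSeq Stranded mRNA). Groups were taken from the sample titles and source names: neonatal hearts with adult T cells (n = 4), neonatal controls (n = 4), adult hearts with adult T cells (n = 4) and adult controls (n = 3). The numbers in the titles were used as names of replicates. Doses of T cells, ages in days, infarct sizes and sequencing batches are not stated in the labels.

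Per the submitters' processing notes, base calls were converted with bcl2fastq 2.20.0.422, adapters were trimmed with cutadapt 2.5, reads were aligned to GRCm38.p6 with STAR 2.7.2b and counted with featureCounts 1.6.4, and DESeq2 1.24.0 was used by the submitters. The authors deposited 1 table of raw, unscaled expected counts per gene for 39331 RefSeq genes, in which reads were split into fractions. Of the non-zero values 61.1% were whole numbers. The strand setting, the feature counted and the rule for fractions are not stated. The length column equals the genomic span from start to end in 100% of genes, so it was not used as a transcript length. Gene identifiers and positions are those of the table, on GRCm38.p6.

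Counts were rounded to whole numbers before testing. Genes were kept by filterByExpr of edgeR over the 4 groups (minimum count 10, minimum total 15), which left 16437 genes. Libraries were scaled by the trimmed mean of M values. All 15 libraries were fitted in 1 model with 1 coefficient per group, by the robust quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, and 5 contrasts were tested: T cells against control in neonates, T cells against control in adults, the difference of both effects, neonatal against adult controls, and neonatal against adult recipients. Tests of genes and lists were two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Log2 CPM used a prior count of 1.

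Before the data were examined, 38 gene lists, the contrasts, the alternatives and the rule for named genes were fixed. The lists cover T, B, myeloid and dendritic cells, interferon responses, antigen presentation, inflammation, matrix, stromal and vascular cells, cardiomyocyte states, growth, cell division, metabolism, blood, skeletal and atrial muscle, mitochondrially encoded genes and markers of other tissues. Camera was run over 34 lists with at least 3 tested members and a preset correlation of 0.01, with an estimated correlation and fry (limma 3.58.1) beside it. Markers of other tissues and of natural killer cells with 2 tested members per list were not tested, and sex-linked genes were left out of the list tests. Transcripts of both sexes were present in every group, and no sex term was fitted. For each list the members were also adjusted over the list alone.

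Named genes were the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap of libraries between groups, or 6 each way for the age comparison in recipients and, without the overlap rule, for the difference. Predicted genes, clone names, pseudogenes, ribosomal proteins and antigen receptor segments were excluded. Up to 4 members per list with the smallest p were added, and 17 genes fixed beforehand for T cells, interferon, myeloid cells, matrix, division and cardiomyocytes. Not all genes named by this rule are printed, and 2 of them are not reported here.

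CD3 transcripts were summed per library, divided by the unscaled library total and compared by an exact two-sided permutation test. Per library, the deviation of log2 CPM from the gene's mean over all libraries was correlated with transcript length. These correlations were compared the same way. Transcript length and GC content came from the longest transcript per symbol of GENCODE release M21. To remove a trend, a natural spline with 5 degrees of freedom was fitted per library to the deviation of log2 CPM from the gene's mean, and entered as an offset.

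Depth ran from 21871617 to 34302786 counts per library, and the floor of 3 counts from 0.0875 to 0.137 CPM. The floors cover counting error only, while SDs and standard errors include the spread between libraries. The median standard error of a log2 fold change was 0.114 for T cells in neonates, 0.125 in adults and 0.169 for the difference. The steps were tested on simulated data with the depth and spread of the real libraries and 200 changed genes. Simulated genes were independent of each other, each had the same spread in all libraries, and no library stood apart. Changes of 2-fold were recovered in 82.1%, 70.1%, 64.2%, 79.1% and 77.6% of genes for the 5 contrasts in the order above, with 12, 4, 6, 12 and 6 unchanged genes called. With a length trend added to 1 group, 1002 unchanged genes were called before and 2 after its removal.

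Alternatives were DESeq2 1.42.0, limma voom with sample quality weights, a test against a fold of 1.5 (glmTreat), other scalings (median of ratios, upper quartile, library size only), no filter or a mean of at least 1 CPM, only the libraries of both groups compared, a looser threshold of 0.1 for the overlap of both T cell effects, the title numbers as a block, and each library left out in turn. Removal of length and GC trends, and a fit of the block's libraries without the block, were added after the data had been seen. Group labels were also reassigned over all 35 splits of the libraries of a comparison that keep the group sizes, or 100 splits for the difference. Blood, sham or uninfarcted hearts were not analysed here.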

Results

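Messenger RNA was sequenced from left ventricles of C57BL/6 mice after experimental myocardial infarction. The labels place 15 libraries in 4 groups. Neonatal hearts with transferred adult T cells gave 4 libraries (numbers 1, 2, 4 and 5), and untreated neonatal hearts gave 4 (6, 7, 8 and 9). Adult hearts with adult T cells gave 4 (1, 2, 3 and 4), and untreated adult hearts gave 3 (5, 6 and 7). The protocol gives a time of 36 h and speaks of neonatal hearts only, so the time in the adult hearts is not stated, and no age in days is given. Total counts were 31897034, 30756081, 21871617 and 22178369 in neonatal recipients 1, 2, 4 and 5, and 26679993, 34302786, 30716859 and 24395718 in neonatal controls 6 to 9. They were 23097615, 24020451, 22448517 and 27775438 in adult recipients 1 to 4, and 26587948, 25491742 and 25428199 in adult controls 5 to 7. Levels are given in CPM, the count relative to the library total. A floor of 3 counts equalled 0.0875 to 0.137 CPM and covers counting error only. Of 39331 genes in the table, 16437 were tested in 1 edgeR fit over all 15 libraries. Values for genes are CPM scaled by the trimmed mean of M values, as mean ± SD, or log2 fold changes ± standard error from that fit. Adjusted p is the Benjamini-Hochberg value over all genes tested, or over the 34 gene lists tested with camera. The first principal component held 53.2% of the variance across all libraries.

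The first comparison asked whether adult T cells altered the transcripts of infarcted neonatal ventricles, with 4 recipients and 4 controls. Macrophage transcripts stood higher on average in recipients, by a median log2 fold change of 0.66 over 15 pan-macrophage markers, all 15 with a positive value. Csf1r, the receptor for colony-stimulating factor 1, measured 71.5 ± 8.70 CPM in recipients and 45.7 ± 17.3 in controls. Lyz2, a macrophage and neutrophil lysozyme whose reads can be shared with Lyz1, measured 241 ± 64.7 and 128 ± 60.2. Adgre1, which encodes F4/80 (gene ID 13733, GRCm38.p6 chromosome 17, 57358581 to 57483529), measured 35.9 ± 7.50 and 21.8 ± 10.4, a log2 fold change of 0.72 ± 0.29. None of the 15 markers passed on its own, and the list passed only as a set (adjusted p = 1.32e-20 with the preset correlation of 0.01, adjusted p = 0.5 with an estimated correlation). Neonatal control 8 had the lowest mean log2 level of these markers, -0.55 relative to all libraries against 0.32 to 1.42 in the other neonatal libraries. Without it the median difference was 0.43, with all 15 still positive (adjusted p = 4.09e-18, adjusted p = 0.559 with an estimated correlation).

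Several other inflammatory groups, but not all, stood on the same side, and no member of any list passed over all genes tested. In the interferon gamma response 24 of 26 members had positive values, with median 0.57. Irf8, a transcription factor of myeloid cells, measured 31.7 ± 4.74 and 21.6 ± 5.63 CPM. All 20 acute inflammatory genes were positive (median 0.42), with the adhesion molecule Icam1 at 16.1 ± 4.73 and 11.3 ± 2.21 CPM. All 10 genes of MHC class II presentation were positive (median 0.48), as were 10 of 11 monocyte genes (0.49) and 13 of 14 reparative genes (0.57), among them Lgals3 (galectin-3) at 177 ± 50.1 and 107 ± 56.5 CPM. With the preset correlation these lists had adjusted p of 7.41e-07, 1.5e-06, 1.5e-06, 0.000144 and 3.46e-05, and each had adjusted p = 0.52 with an estimated correlation. The 6 cytotoxic genes were all positive (median 0.58, adjusted p = 0.00107, adjusted p = 0.52 with an estimated correlation). Gzma, a granzyme of cytotoxic lymphocytes, measured 0.456 ± 0.0927 and 0.111 ± 0.0908 CPM. It was the only member of these lists that passed when adjusted over the list alone, at a level near the floor. Without neonatal recipient 4 the interferon gamma list had adjusted p = 0.306. Neonatal control 8 was the lowest neonatal library for every list of this paragraph. Without it the medians were 0.52 for interferon gamma, 0.22 for acute inflammatory (15 of 20 positive), 0.29 for MHC class II, 0.27 for monocyte, 0.23 for reparative and 0.48 for cytotoxic genes. Their adjusted p were then 1.88e-05, 0.0470, 0.00370, 0.0478, 0.0401 and 0.00716, and adjusted p = 0.895, 0.988, 0.895, 0.895, 0.925 and 0.895 with an estimated correlation. Type I interferon and neutrophil genes did not pass as lists with all libraries. Without control 8, type I interferon genes had 4 of 20 positive values (median -0.16, adjusted p = 0.0157, 0.988 with an estimated correlation). Neutrophil genes then had 7 of 14 (median -0.03, adjusted p = 0.671, 0.988 with an estimated correlation).

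Metabolic and contractile transcripts differed by small amounts in the other direction. All 28 oxidative phosphorylation genes had negative values (median -0.08, adjusted p = 0.000317, adjusted p = 0.654 with an estimated correlation), with Cox5b at -0.20 ± 0.11. All 22 fatty acid oxidation genes were negative (median -0.10, adjusted p = 0.000624, adjusted p = 0.654 with an estimated correlation). Of 22 mature cardiomyocyte genes 3 were positive (median -0.08, adjusted p = 0.00495, adjusted p = 0.52 with an estimated correlation). All 29 fibrillar collagen and matrix genes were positive (median 0.14, adjusted p = 0.00152, adjusted p = 0.654 with an estimated correlation). Mki67, a marker of cycling cells, measured 142 ± 4.23 and 158 ± 14.99 CPM, and 3 of 22 mitosis genes were positive (median -0.05, adjusted p = 0.0289, adjusted p = 0.728 with an estimated correlation). These groups moved with a single library. Neonatal control 8 was the lowest of the 8 neonatal libraries in 20 of 34 lists and the highest in 7, and lay at 53.0 on a first neonatal component on which the other libraries spanned -21.1 to 9.60. Without it the adjusted p was 0.778 for oxidative phosphorylation, 0.546 for fatty acid oxidation, 0.424 for mature cardiomyocyte, 0.979 for collagen and 0.778 for mitosis, and all but the mature cardiomyocyte list changed direction. Without neonatal recipient 1, fatty acid oxidation had 0.253 and mature cardiomyocyte 0.265. For mitosis the values were 0.412 without recipient 2 and 0.0828 without recipient 5.

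The remaining lists that passed in neonatal hearts each depended on single libraries. MHC class I (median 0.18), resident macrophage (0.28), B cell (0.26), dendritic cell (0.10) and immediate early genes (0.15) stood higher in recipients and erythroid genes (-0.12) lower. Their adjusted p were 0.00406, 0.00536, 0.0149, 0.0303, 0.0442 and 0.0471, and adjusted p = 0.654, 0.52, 0.52, 0.52, 0.654 and 0.654 with an estimated correlation. Leaving out 1 library raised them to at most 0.101 (recipient 4), 0.105 (recipient 1), 0.190 (control 9), 0.130 (control 6), 0.424 (control 8) and 0.778 (control 8). Without control 8 the medians were 0.09 for MHC class I, 0.11 for resident macrophage, 0.28 for B cell, 0.04 for dendritic cell, 0.05 for immediate early and 0.03 for erythroid genes, the last with its sign turned.

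**Figure D1:**
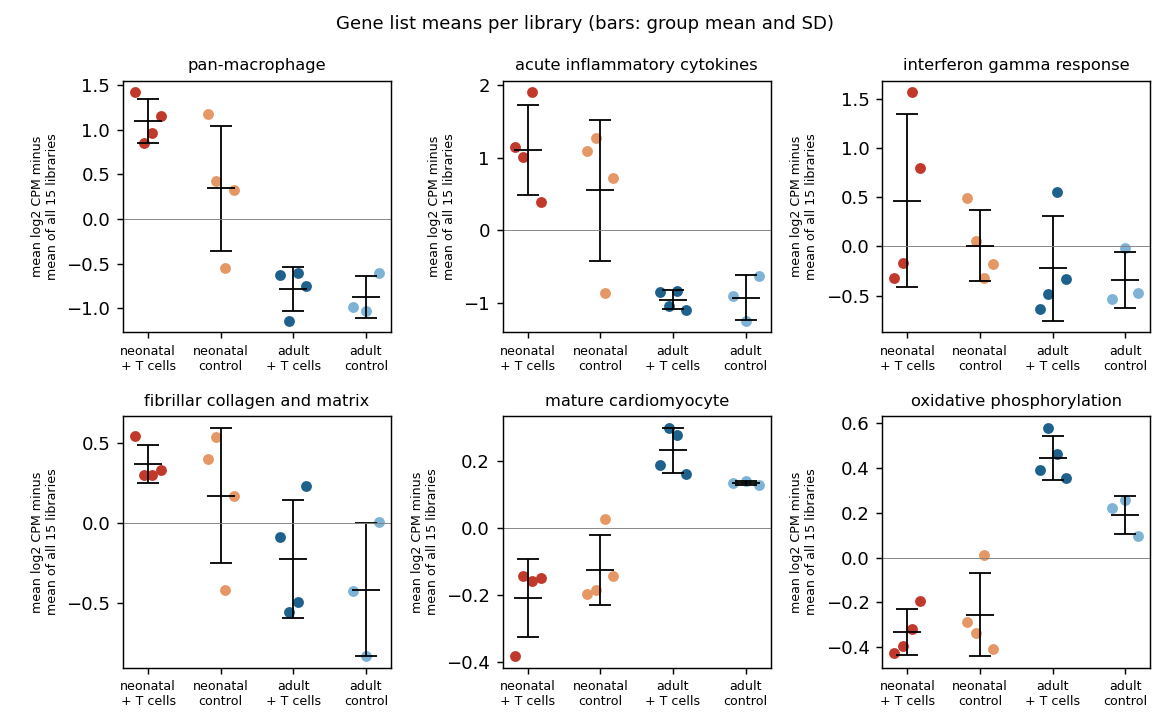
Mean log2 CPM of the genes of 6 lists in each library, minus the mean of the 15 libraries (points: libraries, bars: group mean and SD). Pan-macrophage genes lie higher in both neonatal groups than in both adult groups, on average, and neonatal control 8 is the lowest neonatal library for them.

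T cell transcripts themselves were close to the limit of detection. The summed CD3 chain transcripts, relative to the unscaled library total, measured 0.730 ± 0.377 CPM in neonatal recipients and 0.478 ± 0.307 in neonatal controls (n = 4 and 4, exact two-sided permutation p = 0.371, smallest possible 0.0286). Neonatal control 6 alone had 0.937 CPM and the other controls 0.293 to 0.355. Ifng, the gene of interferon gamma, had 0, 1, 15 and 7 counts in recipients 1, 2, 4 and 5, and 1 count over the 4 controls. Cd3e, Cd8a and Ifng had too few counts to be tested. Of 16 T cell receptor and signalling genes 7 had positive values. Their median was -0.05 and their mean 0.07, and camera gave an upward direction (adjusted p = 0.567).

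For single genes, edgeR called 0 of 16437 between neonatal recipients and controls, with 513 at an unadjusted p below 0.05 and a smallest adjusted p of 0.999. DESeq2 called 0 and limma voom called 0. The median standard error was 0.114 log2. On simulated counts the fit recovered 82.1% of 2-fold and 52.2% of 1.5-fold changes. The simulated genes were independent, with equal spread in all libraries, and no simulated library stood apart, unlike in the real neonatal controls. These shares can therefore be too high for the real neonatal groups. This holds above all for genes with larger errors, such as Adgre1 with a standard error of 0.29. Camera called 18 of 34 lists (13 higher, 5 lower), of which 0 passed with an estimated correlation and 0 with fry. Without neonatal control 6, 9 genes passed.

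The second comparison put the same question to adult hearts, with 4 recipients and 3 controls. Single genes of glycolysis, respiration and the sarcomere rose by modest amounts with T cells, while most members of their groups did not pass over all genes. Aldoa, a glycolytic aldolase, measured 2073 ± 123 CPM in recipients and 1604 ± 109 in controls, a log2 fold change of 0.37 ± 0.090 (adjusted p = 0.0237). Uqcrc1, a core subunit of respiratory complex III, measured 1355 ± 50.8 and 1073 ± 29.0 (0.34 ± 0.096). Tcap, the titin cap of the Z-disc, measured 331 ± 17.8 and 258 ± 2.98 (0.36 ± 0.084), and Tnnc1, cardiac troponin C, 2790 ± 186 and 2132 ± 81.1 (0.39 ± 0.098). Mki67 (gene ID 17345, chromosome 7, 135689784 to 135716450) fell to 89.5 ± 8.67 from 116 ± 8.19 CPM (-0.37 ± 0.087, adjusted p = 0.0211), and its log2 fold change was -0.11 with the transcript length trend removed. These calls were lost without adult recipient 4, control 5 or control 6, and with the transcript length trend removed, when 0 genes passed.

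Over all genes, 580 rose and 826 fell with T cells in adult hearts (edgeR, 1406 in total), 13 and 39 of them past 2-fold. In 1355 of the 1406 the libraries of both groups did not overlap. The genes named here have a mean of at least 5 CPM in the higher group and are not predicted genes, and larger changes occurred among called genes below that level. Among the rises, Enho, which encodes adropin (gene ID 69638, chromosome 4, 41638144 to 41640302), measured 7.86 ± 0.983 and 4.86 ± 0.698 CPM and rose by 0.69 ± 0.16 (adjusted p = 0.0203), the transcription factor Pou2f3 by 0.60 ± 0.15 and Pex11g, a peroxisomal membrane protein, by 0.58 ± 0.14. Under this rule the largest rise was that of Bc1, a small noncoding RNA related to repeats (2.33-fold, adjusted p = 0.0495), whose reads may be shared with other loci. Among the falls were Ago2, the slicer Argonaute (gene ID 239528, chromosome 15, 73101625 to 73184947), at 18.04 ± 3.14 and 34.3 ± 8.35 CPM (log2 -0.93 ± 0.25, adjusted p = 0.0431). Alg10b, a glucosyltransferase of N-glycan assembly (gene ID 380959, chromosome 15, 90224311 to 90230554), fell to 8.92 ± 1.603 from 17.3 ± 5.28 CPM, and Mob1b, a Hippo pathway cofactor, fell by 0.88 ± 0.22 on the log2 scale. Zbed6, which lies inside another gene, had the largest log2 fall under this rule, -1.65 ± 0.32. Without adult recipient 4, control 5 or control 6 none of these genes passed, and the count was 0.

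**Figure D2:**
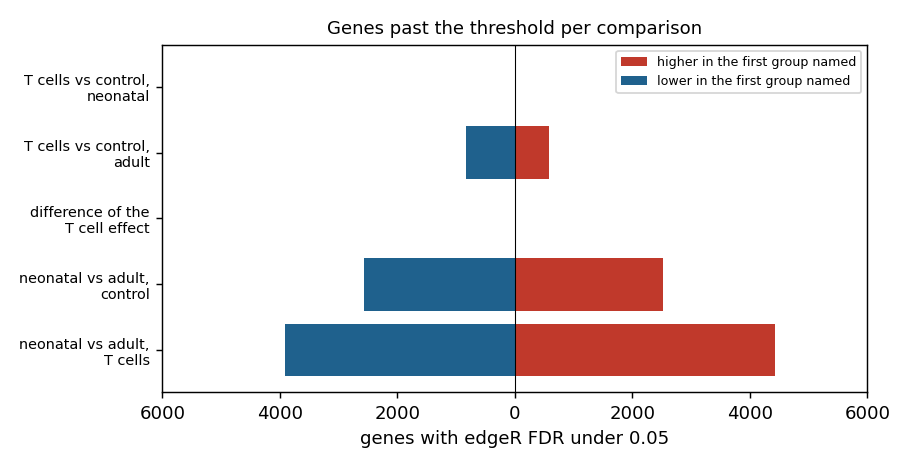
Number of genes called higher (red) and lower (blue) by edgeR at an adjusted p below 0.05 in each of 5 comparisons, of 16437 tested. The bars stand at 0 for T cells in neonatal hearts, 580 and 826 for T cells in adult hearts, 0 for the difference, 2526 and 2559 for age in controls and 4420 and 3919 for age in recipients.

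By group, all 28 oxidative phosphorylation genes had positive values in adult recipients (median 0.27). Of these 2 rose over all genes, Uqcrc1 and Ndufv1, and 20 when adjusted over the list alone (list adjusted p = 2.35e-08, adjusted p = 0.829 with an estimated correlation). Of 20 glycolysis genes 4 rose and none fell, and 12 rose when adjusted over the list alone. Beside Aldoa these were Gapdh (0.36), Tpi1 (0.27) and Aldoc (0.80). The list had adjusted p = 1.18e-05, and adjusted p = 0.829 with an estimated correlation. Of 22 mature cardiomyocyte genes 6 rose and 1 fell, or 10 and 3 when adjusted over the list alone, with Actn2 at 0.37 and Actc1 at 0.33 (list adjusted p = 0.0403, adjusted p = 0.829 with an estimated correlation). Without adult recipient 2, recipient 3 or control 7 that list had adjusted p of 0.0752, 0.120 and 0.0643. Fetal and stressed cardiomyocyte genes had 15 of 16 positive values (median 0.35, adjusted p = 0.0136, adjusted p = 0.829 with an estimated correlation), and no member passed on its own. Their member Myh7, the slow myosin heavy chain, measured 2187 ± 388 and 1552 ± 323 CPM (adjusted p = 0.0855). Adult recipient 4 stood apart here, with Myh7 at 2766 CPM against 1943 to 2046 in the other recipients. Its mean log2 level relative to all libraries was 0.31 against -0.26 to -0.20 for this list, and 0.13 against -0.15 to -0.12 for glycolysis. In the skeletal muscle list the only member that passed over all genes was Pgam2, a muscle phosphoglycerate mutase also made in heart, at 601 ± 41.4 and 446 ± 19.96 CPM (list adjusted p = 0.0244, adjusted p = 0.513 with an estimated correlation). This was the only list past the threshold with fry (0.0146). The member calls were all lost without adult recipient 4, control 5 or control 6, when 0 genes passed.

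Antigen presentation stood higher and mitochondrially encoded transcripts lower in adult recipients. Of 18 MHC class I genes 17 were positive (median 0.37), and the proteasome activators Psme1 (0.38 ± 0.088) and Psme2 (0.36) rose, also when adjusted over the list alone. The list had adjusted p = 0.00323, adjusted p = 0.829 with an estimated correlation, and 0.227 without adult recipient 3. All 10 MHC class II genes were positive (median 0.51, adjusted p = 0.0403, adjusted p = 0.829 with an estimated correlation), none passed on its own, and Cd74, the invariant chain, measured 23.2 ± 8.83 and 13.03 ± 1.245 CPM. Without adult recipient 3, recipient 4 or control 7 this list had 0.223, 0.0578 and 0.0643. Of 13 mitochondrially encoded genes 3 fell, ND4L (-1.18 ± 0.23), ND5 (-0.78) and ND4 (-0.49), and these also fell when adjusted over the list alone (list adjusted p = 0.00323, adjusted p = 0.829 with an estimated correlation). ND4L overlaps ND4, so reads can be shared. The mitochondrial protein-coding share of counts was 12.6 to 17.6% in recipients and 17.98 to 21.4% in controls. Of 14 neutrophil genes 2 were positive (median -0.64, adjusted p = 0.0437, adjusted p = 0.829 with an estimated correlation), with Csf3r, the receptor for granulocyte colony-stimulating factor, at 2.44 ± 0.783 and 6.13 ± 2.06 CPM. Without recipient 1, recipient 2, control 6 or control 7 the neutrophil list had 0.138, 0.0893, 0.184 and 0.185. CD3 chain transcripts, relative to the unscaled library total, summed to 1.39 ± 0.379 CPM in recipients and 0.724 ± 0.222 in controls (n = 4 and 3, exact two-sided permutation p = 0.0857, smallest possible 0.0286). Of 16 T cell receptor and signalling genes 12 were positive (median 0.53, adjusted p = 0.0795), and none passed on its own.

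The adult effect followed transcript length. Across 14236 genes with a known transcript length, which are not independent replicates, the log2 fold change had a Spearman correlation with length of -0.50 in adult hearts and -0.06 in neonatal hearts. In the shortest of 5 length classes 373 genes rose and 8 fell, with a median of 0.21. In the longest class 7 rose and 518 fell, with a median of -0.20. Per library, length was also correlated with the deviation of log2 CPM from the gene's mean over all libraries, a value relative to the other libraries. This correlation was -0.36 to -0.23 in adult recipients and 0.0609 to 0.154 in adult controls (exact two-sided permutation p = 0.0286, the smallest possible with 4 and 3 libraries, and 0.743 in neonates). With each library's length trend removed, 0 genes passed (smallest adjusted p 0.0648), the MHC class II list had 0.0767, and the other lists named above that have transcript lengths stayed past the threshold. With the GC trend removed, 891 genes passed (464 higher, 427 lower) and 5 lists, with 0.0889 for mature cardiomyocyte and MHC class II genes and 0.0941 for skeletal muscle genes. With both removed, 197 genes passed (137 higher, 60 lower).

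**Figure D3:**
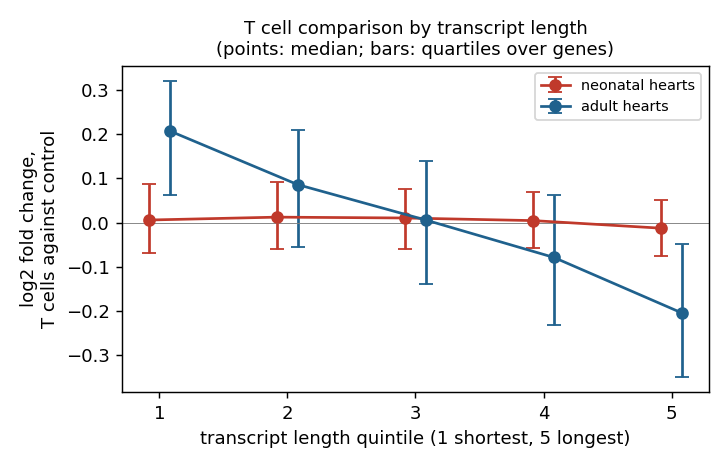
Median log2 fold change of T cell recipients against controls in 5 classes of transcript length, with bars from the lower to the upper quartile of genes, in neonatal and in adult hearts. Adult medians run from 0.21 in the shortest class to -0.20 in the longest, and neonatal medians stay between -0.01 and 0.01.

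For the 1406 calls in adult hearts, the smallest adjusted p was 0.018 and 4491 genes had an unadjusted p below 0.05. DESeq2 called 2320 (1239 higher, 1081 lower) and limma voom 3433, and 0 genes passed against a fold of 1.5. Without adult recipient 4, control 5 or control 6, 0 genes passed, and 464 passed without recipient 2. With library size as the only scaling 458 were higher and 1034 lower. Camera called 9 lists (7 higher, 2 lower), 0 with an estimated correlation.

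The third comparison asked whether the effect of T cells differed between ages, as the difference of the neonatal and the adult log2 fold change. Oxidative phosphorylation genes had a lower effect in neonates in all 28 members, by a median of -0.35. Of these 14 passed when adjusted over the list alone and none over all genes, with Cox5b at -0.53 ± 0.17 (adjusted p = 0.194). Mature cardiomyocyte genes had a median difference of -0.28, with 6 lower when adjusted over the list alone and Tcap at -0.49 ± 0.11 (adjusted p = 0.182). For both of these lists neonatal control 8 was the highest neonatal library. Without it their medians were -0.29 and -0.26, with adjusted p of 1.65e-09 and 0.00420, and 0.725 for each with an estimated correlation. All 15 pan-macrophage genes (median 0.52) and all 14 neutrophil genes (median 0.71) had a higher effect in neonates, with Csf1r at 0.70 ± 0.31 (adjusted p = 0.314) and Csf3r at 1.67 ± 0.58 (adjusted p = 0.22). Neonatal control 8 was the lowest neonatal library for the pan-macrophage and neutrophil lists. Without it the median difference was 0.32 for pan-macrophage genes (adjusted p = 0.0111, adjusted p = 0.922 with an estimated correlation). It was 0.55 for neutrophil genes, of which 13 of 14 stayed positive (adjusted p = 0.00420, adjusted p = 0.725 with an estimated correlation). The neonatal neutrophil effect itself then had a median of -0.03, with 7 of 14 positive (adjusted p = 0.671), so that difference rested on the lower values in adult recipients. The adult list call behind it did not hold with an estimated correlation (adjusted p = 0.829). It was also lost on leaving out single adult libraries, as given above.

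The list tests gave adjusted p = 7.42e-13 for oxidative phosphorylation, 0.00102 for mature cardiomyocyte, 0.00102 for pan-macrophage and 0.00506 for neutrophil genes. With an estimated correlation these were adjusted p = 0.731, 0.731, 0.896 and 0.896. Glycolysis (median -0.24, adjusted p = 0.000622, 0.731 with an estimated correlation), with Aldoc at -0.80, and skeletal muscle (median -0.48, adjusted p = 0.0116, 0.359 with an estimated correlation) also had a lower effect in neonates. Monocyte genes had a higher one (median 0.73, adjusted p = 0.0154, 0.896 with an estimated correlation), with 0.0597 without neonatal recipient 4, and 0.0594 and a median of 0.40 without neonatal control 8. The log2 fold difference followed transcript length here too, with a Spearman correlation of 0.44 across genes. No gene passed in edgeR, 2511 had an unadjusted p below 0.05, the smallest adjusted p was 0.182, DESeq2 called 178 and limma voom 1. Neonatal and adult effects correlated across genes with a Pearson r of 0.0903, with the same sign in 55.3% of genes, and 0 genes were called in both, where chance gives 0 because no neonatal gene was called.

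The fourth comparison asked how infarcted neonatal and adult ventricles differed without T cells, with 4 neonatal and 3 adult controls. The time after infarction is not stated for the adult hearts. In both age comparisons a difference in that time or in injury therefore cannot be told apart from age. Growth and division transcripts were higher in neonates. H19, an imprinted noncoding RNA of fetal growth (gene ID 14955, chromosome 7, 142575530 to 142578146), measured 1782 ± 109.9 CPM in neonates and 830.1 ± 104 in adults (log2 1.10 ± 0.094, adjusted p = 3.44e-07). Plagl1, an imprinted zinc finger gene, measured 175 ± 21.9 and 74.5 ± 2.53, and Hmga2, a chromatin protein of fetal tissue, 4.78 ± 1.13 and 0.653 ± 0.126. Macrophage transcripts were also higher, with the lysosomal marker Cd68 at 43.5 ± 25.4 and 7.73 ± 2.10 CPM (2.49 ± 0.44, adjusted p = 0.00144). Transcripts of oxidative metabolism were lower, with Cox6a2, a muscle subunit of cytochrome c oxidase, at 437 ± 86.0 and 928 ± 11.4 CPM (-1.09 ± 0.14, adjusted p = 1.95e-05).

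Some changes exceeded an order of magnitude, while those of Klhdc8a, Mapt, Pi16 and Hcn2 fell short of it. Spp1, which encodes osteopontin (gene ID 20750, chromosome 5, 104435111 to 104441053), measured 391.98 ± 212 CPM in neonatal and 17.4 ± 22.8 in adult controls, a fold of 22.4 (log2 4.49 ± 1.19, adjusted p = 0.0148), and had adjusted p = 0.0624 without adult control 5. Adult control 7 held most of the adult mean, and without it the log2 fold change was 6.49. Lgals3 measured 107.0 ± 56.5 and 7.91 ± 5.06, and Sprr1a, a cornified envelope protein also made by injured heart, 40.8 ± 23.4 and 1.90 ± 1.90. Klhdc8a (gene ID 213417, chromosome 1, 132298490 to 132307357) was 4.67 ± 0.872 and 39.4 ± 6.02 CPM (log2 -3.08 ± 0.13, adjusted p = 7.8e-11). Mapt, which encodes the microtubule protein tau (gene ID 17762, chromosome 11, 104229409 to 104332090), was 3.72 ± 0.209 and 33.6 ± 1.73. Pi16, a peptidase inhibitor of fibroblasts, was 7.52 ± 0.410 and 53.2 ± 9.57, and the pacemaker channel gene Hcn2 6.91 ± 1.14 and 39.8 ± 2.198. C1qtnf3, a secreted C1q-related protein, fell by 5.89 ± 0.88 on the log2 scale. Over the alternative settings the highest adjusted p was 0.406 for Spp1, 0.275 for Lgals3, 0.304 for Sprr1a and 0.154 for C1qtnf3. Klhdc8a, Mapt, Pi16 and Hcn2 kept their calls.

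By group, 12 of 16 fetal growth and imprinted genes were higher in neonatal controls and none lower (13 when adjusted over the list alone, median 0.82, list adjusted p = 4.19e-15, adjusted p = 0.00187 with an estimated correlation). Of 22 mitosis genes 17 were higher (21 when adjusted over the list alone, median 0.46), with the motor protein Cenpe at 0.77 ± 0.11 and Aurkb, a mitotic kinase, at 0.63 ± 0.099 (list adjusted p = 1.81e-09, adjusted p = 0.519 with an estimated correlation). Of 20 DNA replication genes 9 were higher (10 when adjusted over the list alone), with thymidylate synthase Tyms at 0.71 (list adjusted p = 0.00139, adjusted p = 0.591 with an estimated correlation). Of 15 pan-macrophage genes 12 were higher (15 when adjusted over the list alone, median 1.26), with Trem2 at 2.15 and Ctss at 2.23 (list adjusted p = 5.56e-06, adjusted p = 0.519 with an estimated correlation). Of 20 acute inflammatory genes 10 were higher over all genes and over the list alone, with Vcam1 at 0.80 ± 0.10 and the chemokine Ccl3 at 4.58 (list adjusted p = 0.000458, adjusted p = 0.542 with an estimated correlation). Of 20 type I interferon genes 11 were higher (13 when adjusted over the list alone), with Oas2 3.04-fold and Oasl2 2.58-fold higher (list adjusted p = 0.00017, adjusted p = 0.553 with an estimated correlation). Of 29 collagen and matrix genes 9 were higher and 1 lower, over all genes and over the list alone, with Loxl2, a collagen cross-linking enzyme, 2.35-fold higher and Fap at -0.96 (list adjusted p = 0.00286, adjusted p = 0.661 with an estimated correlation, 0.0796 without adult control 6). Neonatal control 8 was the lowest neonatal library for the fetal growth, pan-macrophage, acute inflammatory, type I interferon and collagen lists and the highest for mitosis and DNA replication. Without it the medians were 1.49 for pan-macrophage, 1.31 for acute inflammatory, 0.85 for fetal growth and 0.43 for mitosis genes, and every list of this paragraph still passed, DNA replication with adjusted p = 0.0462.

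Oxidative, mature cardiomyocyte, endothelial and fibroblast groups stood lower in neonatal controls. Of 28 oxidative phosphorylation genes 24 were lower (25 when adjusted over the list alone, median -0.36, list adjusted p = 1.06e-09, adjusted p = 0.519 with an estimated correlation). Of 22 fatty acid oxidation genes 16 were lower (18 when adjusted over the list alone), with the fatty acid binding protein Fabp3 at 2077 ± 499 and 3442 ± 136 CPM (list adjusted p = 2.73e-07, adjusted p = 0.519 with an estimated correlation). Of 13 mitochondrially encoded genes 10 were lower (11 when adjusted over the list alone, median -0.63, list adjusted p = 4.11e-06, adjusted p = 0.519 with an estimated correlation). Of 22 mature cardiomyocyte genes 9 were lower and 1 higher, over all genes and over the list alone (list adjusted p = 0.0109, adjusted p = 0.519 with an estimated correlation). Ckmt2, mitochondrial creatine kinase, was 177 ± 57.4 and 601 ± 57.2 CPM and myoglobin, Mb, 3603 ± 1098 and 8107 ± 422. The sodium-calcium exchanger Slc8a1 was higher (860 ± 66.3 and 407 ± 14.5). Of 16 endothelial genes 10 were lower and 1 higher (11 and 1 when adjusted over the list alone), with the apelin receptor Aplnr at -0.85 ± 0.11 (list adjusted p = 6.72e-06, adjusted p = 0.0567 with an estimated correlation). Of 15 fibroblast genes 6 were lower and 2 higher (7 and 2 when adjusted over the list alone), with Dcn, decorin, at 233 ± 22.8 and 448 ± 11.4 CPM and Mfap5 at -1.91 ± 0.19 (list adjusted p = 9.96e-06, adjusted p = 0.115 with an estimated correlation). Neonatal control 8 was the highest neonatal library for the oxidative phosphorylation, fatty acid oxidation, mitochondrially encoded, mature cardiomyocyte and endothelial lists. Without it the medians were -0.44 for oxidative phosphorylation, -0.59 for fatty acid oxidation and -0.79 for mitochondrially encoded genes, and every list of this paragraph still passed.

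In total 2526 genes were higher and 2559 lower in neonatal than in adult controls (edgeR, 5085 of 16437), 711 and 494 of them past 2-fold, and 4369 had no overlap of libraries. Against a fold of 1.5, 600 passed, and with library size as the only scaling the counts were 5152 and 1413, with a median over all genes of 0.18. Leaving out 1 library gave 3588 to 5523 genes, the highest without neonatal control 8. Camera called 17 lists (11 higher, 6 lower), of which 1, fetal growth and imprinted, passed with an estimated correlation.

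**Figure D4:**
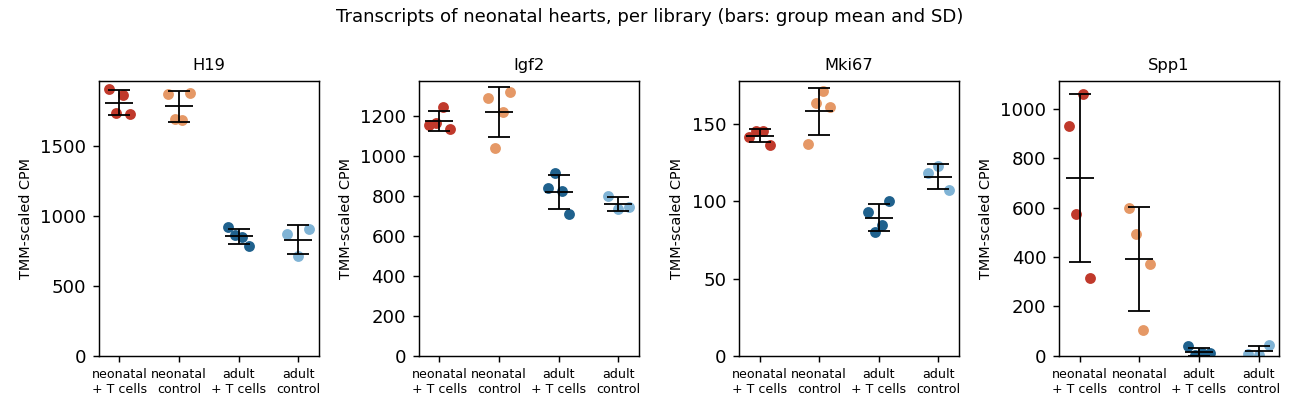
Scaled CPM of H19, Igf2, Mki67 and Spp1 in each of the 15 libraries (points), with the mean and SD of each group (bars). Adult controls keep H19 at 830.1 and Igf2 at 759.9 CPM, and Spp1 lies at 17.4 CPM in adult and 391.98 in neonatal controls.

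The fifth comparison put the question of age to hearts that had received adult T cells, with 4 libraries on each side. The log2 fold change followed transcript length here, with a Spearman correlation across genes of 0.27 with length and -0.38 with GC content. In the shortest length class 418 genes were higher and 1152 lower in neonates, and in the longest class 1373 and 332. Values of genes and lists in this comparison are given without removal of these trends, unless stated. H19 measured 1809 ± 89.5 CPM in neonatal and 854 ± 56.1 in adult recipients, and Cenpe 36.9 ± 4.11 and 17.8 ± 2.12. Spp1 reached 719 ± 340 and 16.4 ± 16.8, a fold of 43.8 (log2 5.45 ± 1.10, adjusted p = 0.00157, and log2 6.41 without adult recipient 1). Arg1, arginase 1 of wound macrophages (gene ID 11846, chromosome 10, 24915207 to 24927470), measured 25.5 ± 15.4 and 0.903 ± 0.830 (log2 4.87 ± 1.18, adjusted p = 0.00487 in edgeR and 0.0917 in limma voom). Vtn, vitronectin (gene ID 22370, chromosome 11, 78499120 to 78502325), was 2.05 ± 0.560 and 25.4 ± 5.51, and Mb 3280 ± 438 and 10203 ± 630 CPM.

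All 15 pan-macrophage genes were higher in neonatal recipients, over all genes and over the list alone (median 1.85, list adjusted p = 4.37e-08, adjusted p = 0.548 with an estimated correlation), with Adgre1 at 2.14 ± 0.31. Of 20 acute inflammatory genes 16 were higher and 1 lower (17 and 1 when adjusted over the list alone, median 2.29), with the neutrophil chemokine Cxcl1 at 1.81 ± 0.691 and 0.361 ± 0.0909 CPM (list adjusted p = 6.97e-05, adjusted p = 0.594 with an estimated correlation). Of 14 neutrophil genes 8 were higher (9 when adjusted over the list alone), with Csf3r at 14.3 ± 2.02 and 2.44 ± 0.783 CPM (list adjusted p = 0.0142, adjusted p = 0.707 with an estimated correlation). Of 11 monocyte genes 7 were higher and 1, Ly6c2, lower (-1.26 ± 0.14), or 8 and 1 when adjusted over the list alone (list adjusted p = 0.0257, adjusted p = 0.742 with an estimated correlation). Of 16 fetal growth genes 11 were higher (12 when adjusted over the list alone, list adjusted p = 1.41e-10, adjusted p = 0.0154 with an estimated correlation). Of 22 mitosis genes 18 were higher, over all genes and over the list alone, with Mki67 at 0.67 ± 0.081 (list adjusted p = 2.13e-07, adjusted p = 0.57 with an estimated correlation). Over the other settings, trend removal and left-out libraries included, Mki67 ran from 0.31 to 0.86, with a highest adjusted p of 0.316. Type I interferon genes had 13 of 20 higher (15 when adjusted over the list alone, list adjusted p = 0.00399, adjusted p = 0.807 with an estimated correlation). Reparative genes had 9 of 14 higher (10 when adjusted over the list alone, list adjusted p = 0.0121, adjusted p = 0.757 with an estimated correlation).

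All 28 oxidative phosphorylation genes were lower in neonatal recipients, over all genes and over the list alone (median -0.70, list adjusted p = 1.56e-18, adjusted p = 0.41 with an estimated correlation), with Cox6a2 at 403 ± 77.6 and 1247 ± 62.9 CPM. Of 22 fatty acid oxidation genes 18 were lower (19 when adjusted over the list alone), with Fabp3 at -1.10 ± 0.13 (list adjusted p = 4.09e-08, adjusted p = 0.57 with an estimated correlation). Of 22 mature cardiomyocyte genes 15 were lower and 4 higher, over all genes and over the list alone, with Tcap at -1.48 ± 0.079 and the adult myosin heavy chain Myh6 at -0.65 ± 0.13 (list adjusted p = 0.000117, adjusted p = 0.41 with an estimated correlation). Of 16 endothelial genes 12 were lower and 1 higher, over all genes and over the list alone (list adjusted p = 3.16e-06, adjusted p = 0.0519 with an estimated correlation). Of 15 fibroblast genes 7 were lower and 3 higher (8 and 4 when adjusted over the list alone), with Mfap5 at -2.05 ± 0.19 (list adjusted p = 0.000832, adjusted p = 0.328 with an estimated correlation).

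In total 4420 genes were higher and 3919 lower in neonatal than in adult recipients (edgeR, 8339 of 16437), 1110 and 700 of them past 2-fold, and 7036 had no overlap of libraries. The counts were 6853 and 2279 with library size as the only scaling (median over all genes 0.23), 3086 and 4673 with the length trend removed, 2972 and 4394 with the GC trend removed and 2838 and 4490 with both removed, and 1636 passed against a fold of 1.5. Camera called 16 lists (9 higher, 7 lower), of which 1 passed with an estimated correlation. Over left-out libraries, 118 values of these lists kept their call and 10 lost it. Both age comparisons shared 2078 higher genes, where chance gives 679, and 2195 lower genes, where chance gives 610. Their log2 fold changes correlated with a Pearson r of 0.845 across genes, which are not independent replicates, with the same sign in 80.2%. The larger count among recipients is not itself a test, and in edgeR no gene passed the test of the difference between both age effects, which is the same contrast as the difference of the T cell effects (178 genes with DESeq2, 1 with limma voom).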

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

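The tests of length, GC content, adult RNA and carry-over in this part were chosen only after the results were seen, while the reassignments of group labels were fixed earlier and the prediction for the list ranks of neonatal control 8 was written before its result.

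The 1406 genes called between adult recipients and controls follow transcript length, and 3 explanations were set against each other: a chance assignment of the libraries, a technical trend with length or GC content, and an effect of T cells. Chance is argued against, since 1 of 35 reassignments, the real one, reached 1406 genes and the highest other gave 11. It is not excluded, because 1 of 35 is the smallest share that these group sizes allow. With the length trend removed the called genes kept 64.8% of their median log2 fold change (0.25, from 0.39) and 0 passed, so the data cannot tell a length-dependent loss of RNA or capture from a response that itself favours short transcripts. A GC trend as the whole cause is argued against, since with it removed 622 of the 1364 called genes with a known length still passed (891 genes in all) and 82.8% of the change was kept (median 0.32, quartiles 0.25 to 0.42), close to a bound of 80% set after it was seen, while the other called genes lost their call as the change shrank. Integrity values of the RNA would help to separate these and are not in the labels.

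Neonatal control 8 stands apart from the other 7 neonatal libraries, and 3 technical explanations were tested. If a length trend in this library were the cause, removing it should clear its extreme ranks, and it was still lowest or highest in 24 of 33 lists against 26 before, which argues against that cause. Adult RNA as the whole cause is argued against: 330 genes higher in neonates lay 82.9% of the way to the adult level (-75.7%, -13.0% and 12.2% in controls 6, 7 and 9), while over 232 genes higher in adults the 5th percentile of its level was 20.2% of the adult level, a bound on the share of such RNA. A smaller share stays open, since the 232 genes lay 20.7% of the way (quartiles 8.71 to 33.9, with -5.66% to -5.17% in the other controls) and the upper quartile lay above the limit set, and a stricter choice of genes and a test of length per library had been looked at earlier. No biological explanation was tested, and infarct size is not part of the data used here.

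The libraries labelled adult hold fetal growth transcripts at high levels, with H19 at 830.1, Igf2 at 759.9 and Mki67 at 116 CPM in adult controls. Carry-over of neonatal RNA is argued against: H19 kept 46.6% of its neonatal level, yet the 5th percentile over 448 genes higher in neonates was 15.6%, Arg1 kept 3.66% and Spp1 4.45%. Animals younger than the label says cannot be told from adults with such levels, since no reference adult heart is held against which to set the 830.1 CPM of H19. The labels give no age in days, so both the comparison of ages and its name rest on the sample labels alone.

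Of 162 groups of 4 values examined, 12 held a library far from the others, where chance gives 8.1. The gap to the nearest other library, as a share of the group's range, was 0.879 for collagen and matrix genes and 0.934 for mature cardiomyocyte genes in neonatal recipient 1. It was 0.858 for T cell receptor genes and 0.904 for the CD3 sum in neonatal control 6. It was 0.864 for regulatory T cell genes and 0.891 for fatty acid oxidation genes in neonatal control 8. Ifng gave 1 in neonatal control 7, which held 1 count, and 1 in adult recipient 2, which held 3 counts, with 0 in the other libraries of each group. Monocyte genes gave 0.832 in adult recipient 3. Adult recipient 4 gave 0.894 for fetal and stressed cardiomyocyte genes, 0.895 for glycolysis genes and 0.874 for Myh7, which stood at 2766 CPM against 1943 to 2046 in the other recipients.

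For the difference of the T cell effect between ages, camera with the preset correlation called 10 lists, none of which passed with an estimated correlation. This count does not argue against chance, since 78 of 100 splits of the labels reached it. The adjusted p were 7.42e-13 for oxidative phosphorylation, 0.000622 for glycolysis, 0.00102 for mature cardiomyocyte, 0.00102 for pan-macrophage, 0.00506 for neutrophil, 0.0116 for skeletal muscle and 0.0154 for monocyte genes. They were 0.0141 for fatty acid oxidation (0.400 without neonatal control 8), 0.0249 for mitochondrially encoded (0.164 without adult recipient 4) and 0.0444 for acute inflammatory genes (0.361 without neonatal control 8). Adjusted p with an estimated correlation was 0.896 for these last lists.

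Reassignment of labels bears on the counts of genes and lists. For age, chance is argued against for genes but not excluded, since 1 of 35 splits is the smallest share possible. Only the real split reached 5085 genes in controls and 8339 in recipients, with highest other counts of 4061 and 0. The split with 4061 places neonatal control 8 with the adult controls and points to a structure of the samples. For T cells in neonates, all 35 splits gave at least the real 0 genes, with a highest of 6. For the difference all 100 did, with a highest other of 716 in a split that keeps the real adult labels. Another split with these adult labels gave 0 genes and a split without them gave 307, so the adult labels alone do not account for the 716. Genes called in both T cell effects were 0 in all 100 splits. No count of lists argues against chance. For T cells in neonates 5 of 35 splits reached the 18 lists (highest other 22), and in adults 30 of 35 reached the 9 (16). For the difference 78 of 100 reached the 10 lists (21). For age 9 of 35 reached the 17 in controls (21) and 11 of 35 the 16 in recipients (21).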

How the results depend on the processing

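The removal of length and GC trends and the fit of the block's libraries without a block were chosen only after the results were seen. Depth limits T cell transcripts, where 3 counts equal up to 0.137 CPM. With 3 or 4 libraries per group a 1.5-fold change was recovered in 49.3% to 52.2% of simulated genes for the T cell effects. For their difference the share was 26.9%. No simulated library stood apart, so these shares can be too high for the real libraries. The age comparisons kept their total counts within 1.5 times under every filter, scaling and package, but with library size as the only scaling the split moved to 5152 higher and 1413 lower in controls and 6853 and 2279 in recipients. Against a fold of 1.5 they gave 600 genes in controls and 1636 in recipients, by construction of a stricter question. The adult T cell count was the least stable: 2320 genes with DESeq2, 3433 with limma voom, 0 against a fold of 1.5, 0 with the length trend removed, 891 with the GC trend removed and 197 with both removed. The difference gave 178 genes with DESeq2 and 1 with limma voom. The cause was not tested for the packages.

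Lists past the threshold with an estimated correlation were 0 for T cells in neonates, 0 in adults, 0 for the difference, 1 for age in controls and 1 for age in recipients, and fry, which asks a different question, gave 0, 1, 0, 19 and 17. With the GC trend removed 5 lists passed in adults, and the cause was not tested. Fitting the title numbers as a block on the shared numbers gave 3927 genes for age in controls and 7276 in recipients, and the same libraries without the block gave 3021 and 7330, with fewer libraries than the full fit by construction. Deviations of libraries with the same number correlated at 0.144 with 2 shared numbers in controls, and at 0.0345, 0.139 and -0.00565 in recipients, where not every library correlated best with its own number. The samples are therefore treated as unpaired, and recipients and controls of the same age share no number, so no block was possible there.

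Leaving out 1 library gave 0 to 9 genes for T cells in neonates, 0 to 1230 in adults, 0 to 0 for the difference and for genes called in both, 3588 to 5523 for age in controls and 7429 to 8078 in recipients, and, for the 5 contrasts in that order, 12 to 22, 8 to 11, 8 to 15, 17 to 18 and 14 to 18 lists. Without neonatal control 8 some neonatal lists turned direction: adjusted p ran from 4.57e-09 to 0.778 over left-out libraries for oxidative phosphorylation, 3.28e-06 to 0.546 for fatty acid oxidation, 1.1e-06 to 0.979 for collagen and 0.00363 to 0.778 for mitosis genes, the upper value without that library. No gene of neonatal hearts that turned had passed. Over left-out libraries the log2 fold change ran from -0.0823 to 1.36 for Cxcl9, -0.0230 to 0.959 for Il1b, -0.156 to 0.378 for S100a8, -0.0101 to 0.375 for Col1a1, -0.223 to 0.0154 for Myh6 and -0.0853 to 0.151 for Myh7. With limma voom S100a8 had -0.194, Postn -0.00699 and Myh7 -0.0248, and Postn in the age comparison of recipients had -0.0242 with both trends removed. The cause was not tested. Among named genes of the adult T cell comparison, 228 values kept call and direction and 80 kept direction only over the other settings, and 64 and 104 over left-out libraries. For age in controls these were 389 and 31, then 177 and 19, and for age in recipients 255 and 14, then 144 and 0.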

Other observations

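The test with the length trend removed was chosen after the results were seen, while lists and contrasts were fixed beforehand, and which lists to print was decided afterwards. Several groups not yet described separated neonatal from adult controls (n = 4 and 3). Of 20 glycolysis genes 11 were higher and 4 lower in neonates (12 and 4 when adjusted over the list alone, list adjusted p = 0.000735, adjusted p = 0.519 with an estimated correlation), with the glucose transporter Slc2a1 at 47.5 ± 12.2 and 13.3 ± 2.77 CPM and the phosphofructokinase Pfkp at 197 ± 33.2 and 93.0 ± 12.004. Of 14 reparative genes 8 were higher and 1 lower (9 and 1 when adjusted over the list alone, list adjusted p = 0.0041, adjusted p = 0.553 with an estimated correlation). Of 11 epicardial genes 5 were higher (6 when adjusted over the list alone, list adjusted p = 0.00655, adjusted p = 0.52 with an estimated correlation), with the transcription factor Tbx18 at 22.4 ± 3.85 and 13.6 ± 2.04 CPM. Of 16 fetal and stressed cardiomyocyte genes 8 were higher, over all genes and over the list alone (list adjusted p = 0.00609, adjusted p = 0.519 with an estimated correlation), with Tnni1, the slow skeletal troponin I of fetal heart, at 1534 ± 165 and 1041 ± 47.6 CPM. For the glycolysis, reparative and fetal and stressed cardiomyocyte lists neonatal control 8 was the lowest neonatal library. Without it these lists had adjusted p of 0.000443, 0.000289 and 0.00100 (0.358 for each with an estimated correlation), and epicardial genes 0.00591 (0.397).

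Other genes differed by age within lists that did not pass as sets in controls. Of the mural cell markers 4 were lower and 3 higher in neonates, with Rgs5, a pericyte regulator of G protein signalling, at 245.1 ± 51.9 CPM in neonatal and 686.5 ± 92.6 in adult controls (log2 -1.49 ± 0.15), Higd1b at -1.24, Kcnj8 at -0.86 and Mcam at 0.47. Fast skeletal troponin T, Tnnt3, was higher in neonates at 8.54 ± 3.54 and 1.27 ± 0.504 CPM (2.74 ± 0.45). Among resident macrophage genes Mrc1 (0.95) and Lyve1 (1.17) were higher and Cbr2 (-2.12) and Timd4 (-1.54) lower. Of B cell genes 3 were lower, with the immunoglobulin heavy chain Ighm at 2.97 ± 0.406 and 5.03 ± 1.16 CPM. Cd247, the CD3 zeta chain, was 0.643 ± 0.282 and 3.25 ± 0.601 (-2.34 ± 0.25). The stress-induced phosphatase Dusp1 was 32.9 ± 3.44 and 81.0 ± 26.4. Between recipients, 6 of 9 erythroid genes were lower in neonates, with the adult beta globin Hbb-bs at 645 ± 191 and 1890 ± 381 CPM (list adjusted p = 0.0448, adjusted p = 0.791 with an estimated correlation, 0.109 without neonatal recipient 5 and 0.106 with the length trend removed).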
